A study of Bacillus subtilis and Escherichia coli
Bacillus subtilis with 3 samples.

How the data were processed

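Single bacterial cells were profiled by split-pool barcoding, in which the first barcode records which sample a cell came from, per the labels' protocols. Cells were fixed in formaldehyde, permeabilised and given poly(A) tails in place before reverse transcription and barcode ligation. The submitters' processing notes name STAR, with no version. The genome build, the way UMIs were collapsed and the filter on cells are not given in the sources used here. Each table deposited by the authors holds expected counts of molecules per gene and cell. Of the values above 0, 71.6% were whole in the 2-species table, 97.1% in the 6-point table and 95.4% in the 8-point table, and the rest were fractions with small denominators. Counts of genes that share reads with a near copy are therefore uncertain.

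The contents did not match the titles of the samples. The sample titled as the B. subtilis curve from OD600 0.5 to 3.2 holds cells of both species. The sample titled as the curve from OD600 0.5 to 6.0 holds 6 points from OD600 0.4 to 3.2. The sample titled with both species holds 8 B. subtilis points up to OD600 6.0. The tables are called here by what they hold, with the OD600 of each cell from the authors' annotation of cells. The 6-point table had 25446 cells and 3769 genes and the 8-point one 10972 cells and 3666 genes, without ribosomal RNA. The 2-species table had 2682 cells and 7568 genes. No UMI was held by 744 cells of the 6-point table. Gene symbols came with the growth tables. Of 3822 B. subtilis locus tags in the 2-species table, 3576 were matched to a RefSeq table. E. coli locus tags have no names in the tables used, so the 14 E. coli gene lists were void and those genes were only counted.

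Counts were summed over the cells of an OD point and rounded to whole numbers, since edgeR takes counts. Genes passed edgeR's filter (minimum count 10, minimum total 15) and libraries were scaled by TMM. Expression is in CPM, counts scaled to library size. Per-gene CPM are TMM-scaled, while CPM of a summed list are per total UMIs. The trend was the coefficient of log2 OD600 in edgeR's quasi-likelihood fit, with two-sided p-values adjusted by Benjamini-Hochberg, and slopes are in log2 CPM per doubling of OD600. Any change was an F test of a natural spline with 3 degrees of freedom. Residual degrees of freedom hold departures from the trend as well as error. The sources do not say which points came from separate cultures, so the spread measured may be technical. Gene lists (54, of which 40 for B. subtilis) were tested by camera with a preset correlation of 0.01 where at least 3 members were tested. The lists, the tests of the trend and the spline, and the naming rule were fixed before the data were examined.

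The rule named, in each direction, the 10 genes with the steepest slope among those past an adjusted p of 0.05. Their average expression had to be at or above the median, and the sign of the slope had to hold with each library left out. For a list, up to 4 members of highest expression could be named. fabHA was named in the matched comparison by the same rule. The refits behind the sign rule first filtered genes anew each time. The set of genes tested in the full fit was put in place of that after it was seen that refiltering kept ptsG, treP and treA from being named in the 8-point table. Both versions were run and the names from both are given. Also chosen after values were seen were the fit of the 8-point table on a par with the 6-point table, the comparison at matched points, the UMI pairs within cells, the refits with cells of at least 50 UMIs and with libraries thinned to equal UMIs, and the thresholds of 30 UMIs and 10% used for cells at OD600 2.0.

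Matched points, those at most 0.1 in OD600 apart, were fitted in edgeR with the table as a covariate. Cells were thinned to 200 UMIs and counted as high for a list with at least 3 of its UMIs. The share for an even spread was binomial, from the summed profile of the library. For UMI pairs, gene pairs at least 20 genes apart in the gene order of the RefSeq table were used, in libraries with at least 5 expected pairs, against 1000 random lists of like expression. Cells of the 2-species table were given the species with most UMIs. Doublets were not called otherwise. On simulated counts with known slopes, the trend test recovered 37.8% of slopes of size 1 and 93.5% of slopes of size 2 in the 6-point table, over 1627 genes, and 2.38% of its calls were false. Over 1363 genes of the 8-point table these were 40.8%, 99.0% and 4.93%. The simulated genes were drawn independently of each other and had straight trends. These rates may not carry over to the real curves, where genes of a list move together and some groups peak midway. The pair ratio, on simulated cells with true values of 1 and 4.81, gave means of 0.956 and 4.56.

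Alternatives were RLE scaling, total UMIs only, no filter, each library left out, counts without ribosomal protein genes, other forms of OD600, both tables in 1 fit, DESeq2, fry and an estimated correlation. The comparison of heat-shocked with other cells, planned for both species, was not made, because no file used here maps cells to the treatment. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.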

Results

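The data were single-cell RNA counts from bacteria. Cells were fixed and permeabilised, their RNA was given a poly(A) tail in place, and successive rounds of pooling and splitting gave the transcripts of each cell their own combination of barcodes. Unique molecular identifiers (UMIs) mark the separate molecules. PY79 is a laboratory strain of Bacillus subtilis and MW1255 a strain of Escherichia coli, and the cultures were grown in LB, a rich broth. 3 count tables were analysed. The first held 25446 B. subtilis cells from 6 points of a growth curve, at an optical density (OD600) of 0.4, 1.0, 1.7, 2.0, 2.7 and 3.2. The second held 10972 B. subtilis cells from 8 points, at OD600 0.5, 1.0, 1.3, 1.6, 2.8, 3.6, 5.3 and 6.0. The third held 2682 cells of both species with no culture density or treatment given for any cell. The labels describe a heat-shock sample of both strains at OD600 0.5, but no source used here ties a cell to the treatment. The cells of 1 OD point were summed to 1 library, so each point has 1 library and no replicate.

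Late libraries were the shallowest. A library of the 6-point table held from 944727 UMIs at OD600 0.4 down to 74882 at OD600 3.2, and the median per cell ran from 110 at OD600 0.4 to 22 at OD600 2.7. The 8-point table held 119236 UMIs at OD600 0.5, 490709 at OD600 1.0, 30127 at OD600 2.8, 34111 at OD600 3.6 and 22832 at OD600 6.0, with medians per cell of 64.5 at OD600 0.5, 108 at OD600 1.0 and 19 at OD600 5.3. The 2-species table held 18346100 UMIs. Intervals on summed counts and on shares below are exact 95% Poisson or Clopper-Pearson intervals and cover counting error only.

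The growth curves ask how the transcriptome moves as a culture leaves exponential growth. In both tables the glucose permease gene ptsG, the trehalose genes treA and treP, the mannose permease gene manP and the glycerol phosphate uptake gene glpT fell with density, and rocB, putB and dppE, of arginine, proline and peptide use, rose. In the 6-point table rocB and rocA, which act in arginine breakdown, rose by 3.78 (SE 0.70, adjusted p = 0.0177) and 2.95 (SE 0.70, adjusted p = 0.0269) in log2 expression per doubling of OD600. rocA went from 22.5 to 9323 TMM-scaled CPM between OD600 0.4 and 3.2. The proline gene putB rose by 3.35 (SE 0.50), and the peptide transporter genes appF and dppE by 3.40 (SE 0.60) and 2.84 (SE 0.40). pckA, the gluconeogenic phosphoenolpyruvate carboxykinase, rose by 2.73 (SE 0.72), pksE of the bacillaene cluster by 3.27 (SE 0.89) and amyC by 3.25 (SE 0.59). The 2 unnamed genes listed as gene:BSU11381 and gene:BSU11382 rose by 3.23 (SE 0.57) and 3.16 (SE 0.58). Over all libraries of this table, the 10 named genes that rose held from 120 UMIs (dppE) to 2755 (pckA). At OD600 0.4 appF and dppE held 1.13 CPM and rocB 2.25 CPM, so the size of such slopes rests on few UMIs. Among the genes that fell, ptsG had a slope of -2.12 (SE 0.40) and went from 11205 to 232 CPM. treA and treP had slopes of -2.28 (SE 0.54) and -2.25 (SE 0.56), the mannitol gene mtlD -2.07 (SE 0.31) and manP -1.89 (SE 0.45). glpD and glpT, for glycerol phosphate oxidation and uptake, had slopes of -1.94 (SE 0.35) and -1.87 (SE 0.26). The cold shock gene cspB (-2.28, SE 0.54), the malate carrier gene maeN (-2.01, SE 0.35) and yccF (-1.85, SE 0.37) completed the 10 named among genes that fell.

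In the 8-point table, which reached a higher density, the names overlapped. putB (4.04, SE 1.12), rocB (3.57, SE 0.63), putC (3.31, SE 0.89), rocC (3.19, SE 0.44), dppE (3.18, SE 0.45), appC (3.62, SE 0.53), gene:BSU11382 (3.47, SE 0.51) and gene:BSU11381 (3.33, SE 0.42) rose. Some were highest before the end of the curve: putB held 5379 CPM at OD600 3.6 and 54.0 at OD600 6.0, putC 11004 and 540 CPM at these points, and rocB 2818 CPM at OD600 5.3 and 648 at OD600 6.0. comGA, the ATPase of the DNA uptake pilus, rose by 3.92 (SE 0.44, adjusted p = 0.000189), with no UMI at OD600 0.5 and 2105 CPM at OD600 6.0. bpr, an extracellular protease, rose by 3.22 (SE 0.51). Over all libraries of this table, the 10 named genes that rose held from 68 UMIs (appC) to 824 (putC). comGA held 80, rocC 82, dppE 142 and rocB 178, and appC, rocC, dppE, rocB and putB also held 0 CPM at OD600 0.5. The size of their slopes thus rests on few UMIs. The steepest falls were those of ptsG (-3.93, SE 0.59), treP (-3.74, SE 0.73) and treA (-3.05, SE 0.73), followed by ansA, an asparaginase (-2.47, SE 0.60), and the mannose genes manR (-2.33, SE 0.42) and manP (-2.21, SE 0.56). cspB (-2.20, SE 0.41), glpT (-2.20, SE 0.47), the mannitol permease gene mtlA (-2.18, SE 0.45) and the beta-glucoside permease gene bglP (-2.17, SE 0.58) also fell. These names rest on refits that kept 1 set of tested genes. With genes filtered anew in each refit, 10 of the 20 names of this table were replaced, by spbC (3.07, SE 0.49) and yxbC (3.02, SE 0.37) among genes that rose. Those that fell in their place were pta (-2.08, SE 0.48), yoxD (-1.99, SE 0.50), mleA (-1.98, SE 0.49), pyrG (-1.84, SE 0.29), rplA (-1.79, SE 0.32), rplK (-1.77, SE 0.29), dapH (-1.72, SE 0.34) and ansB (-1.71, SE 0.47). For the 6-point table manR (-1.81, SE 0.33) replaced cspB.

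Over all genes, edgeR's quasi-likelihood test of the trend with log2 OD600 found 208 genes that rose and 164 that fell among 1831 tested in the 6-point table (Benjamini-Hochberg adjusted p under 0.05). Among 1507 tested in the 8-point table, 215 rose and 278 fell. A spline with 3 degrees of freedom found 492 and 534 genes with any change along the curve, of which 197 and 134 had no call in the trend test. In the 6-point table the spline leaves few residual degrees of freedom, and fewer with a library left out. Leaving out any 1 library raised the count there, and a quadratic called 91 genes, so the 6-point spline count is unstable. The p-values measure the fit of a trend over the libraries of 1 curve each, and the 6-point counts depend on single libraries: none was called without OD600 0.4 or without OD600 2.7 (edgeR alone was run there, with 347 and 641 genes at an unadjusted p under 0.05), 331 rose and 297 fell without OD600 1.7, 96 rose and 34 fell without OD600 2.0, and 66 fell without OD600 3.2. For the 8-point table, 136 rose without OD600 0.5, and 131 rose and 155 fell without OD600 1.0; the spline count was 1080, 828 and 892 without OD600 1.0, 2.7 and 3.2 of the 6-point table, and 276, 283 and 300 without OD600 2.8, 3.6 and 6.0 of the 8-point table.

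Ribosomal protein genes together went from 211105 CPM (210180 to 212034) at OD600 0.4 to 8331 CPM (7958 to 8717) at OD600 1.7, and stood at 42377 CPM at OD600 3.2. Their sum in the 8-point table went from 208610 to 21731 CPM. Of 55 tested, 18 fell in the 6-point table (33 when adjusted over the list alone) and 48 in the 8-point table (50 adjusted over the list alone), and none rose. rpsL fell with a slope of -1.23 (SE 0.37, adjusted p = 0.0460) in the 6-point table, where rpsC (-0.96, SE 0.43, adjusted p = 0.125) did not pass. rpsC (-1.03, SE 0.26) and rplC (-1.05, SE 0.27) fell in the 8-point table. The list was called down by camera in both tables (adjusted p = 6.13e-12 and 8.47e-12), a call lost with adjusted p = 0.539 and 0.501 with an estimated correlation. Of 12 translation factor genes, 1 fell in the 6-point table (0 adjusted over the list alone) and 7 in the 8-point table (8 adjusted over the list alone), among them fusA, elongation factor G (-0.78, SE 0.23). The list test (camera) gave adjusted p = 0.00659 and 0.0172, against adjusted p = 0.542 and 0.573 with an estimated correlation, and the call was lost without OD600 0.4 (adjusted p = 0.104) and without OD600 0.5 (adjusted p = 0.0996).

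Of the sugar uptake and overflow genes, 3 of 7 fell in the 6-point table (5 adjusted over the list alone) and 5 of 7 in the 8-point table (5 adjusted over the list alone). ptsI, the shared enzyme of the sugar phosphotransferase system, fell in both (-1.04, SE 0.27, and -1.25, SE 0.25), while ldh, lactate dehydrogenase, had slopes of 0.09 and 0.03 that did not pass. By camera the list had adjusted p = 0.00551 and 0.00198, and adjusted p = 0.508 and 0.201 with an estimated correlation. Of 14 fatty acid synthesis genes, 6 and 5 fell (10 and 6 adjusted over the list alone), with fabF at -1.28 (SE 0.32) and -1.08 (SE 0.24). Camera gave adjusted p = 8.84e-05 and 0.00762, and adjusted p = 0.508 and 0.396 with an estimated correlation; the 8-point call was lost without OD600 0.5 (adjusted p = 0.121). Of 21 cell division and wall genes, 0 and 9 fell (0 and 10 adjusted over the list alone), with murAA at -0.96 (SE 0.26) in the 8-point table. For this list camera gave adjusted p = 0.0315 and 0.0249, and adjusted p = 0.542 and 0.577 with an estimated correlation; both calls were lost without the first library (adjusted p = 0.104 and 0.0863).

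All tested members of the dipeptide and oligopeptide uptake list rose, 12 of 12 in the 6-point table and 11 of 11 in the 8-point table, with the same counts adjusted over the list alone. oppA, the oligopeptide binding protein, went from 116 to 20082 CPM in the 6-point table (2.72, SE 0.50) and rose by 1.39 (SE 0.48) in the 8-point table. The list test (camera) gave adjusted p = 7.23e-13 and 2.41e-08, and adjusted p = 0.508 and 0.201 with an estimated correlation. For arginine and proline use 8 of 9 rose in each table, also adjusted over the list alone, and the summed genes held 364 CPM at OD600 0.4, 31118 CPM at OD600 3.2 and 47615 CPM at OD600 3.6 of the 8-point table, then 5345 CPM at OD600 6.0. By camera the list had adjusted p = 8.11e-06 and 3.89e-05, and adjusted p = 0.508 and 0.396 with an estimated correlation. Branched-chain amino acid synthesis genes rose in 8 of 8 and 6 of 8 cases (8 and 8 adjusted over the list alone), with ilvB at 2.60 (SE 0.34) and 1.88 (SE 0.34). Camera gave adjusted p = 3.68e-08 and 8.28e-05, and adjusted p = 0.508 and 0.241 with an estimated correlation. Of 5 extracellular protease genes 3 and 4 rose (5 and 4 adjusted over the list alone), among them epr (1.50, SE 0.29, and 1.17, SE 0.30). The list test (camera) gave adjusted p = 0.00298 and 0.000530, and adjusted p = 0.508 and 0.201 with an estimated correlation.

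All 4 surfactin synthesis genes rose in both tables, also adjusted over the list alone, with srfAB at 1.74 (SE 0.43) and 1.57 (SE 0.24). They held 1424 CPM at OD600 0.4, 68247 CPM at OD600 3.2 and, in the 8-point table, 254326 CPM (247826 to 260955) at OD600 6.0. Of the bacillaene genes 11 of 13 and 7 of 11 rose (13 and 10 adjusted over the list alone), with pksL at 2.20 (SE 0.49) and 2.17 (SE 0.45). All 5 plipastatin genes rose in both tables, also adjusted over the list alone, with ppsB at 2.50 (SE 0.56) and 1.86 (SE 0.48). By camera the list had adjusted p = 0.00316 and 0.000171 for surfactin, 1.11e-07 and 1.39e-05 for bacillaene, and 2.35e-05 and 0.000377 for plipastatin. With an estimated correlation the surfactin list had adjusted p = 0.508 and 0.299, the bacillaene list adjusted p = 0.508 and 0.350, and the plipastatin list adjusted p = 0.508 and 0.357.

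Of the late motility genes read by the sigma factor SigD, 18 of 21 rose in the 6-point table and 7 of 22 in the 8-point table (20 and 9 adjusted over the list alone). hag, the flagellin gene, rose from 812 to 19589 CPM (1.54, SE 0.37) in the 6-point table; in the 8-point table its slope of 0.77 (SE 0.33, adjusted p = 0.0853) did not pass. The summed list was highest at OD600 2.8 of the 8-point table, with 51517 CPM (48986 to 54145), and held 13494 CPM at OD600 6.0. Of the genes of the long flagellar and chemotaxis operon 19 of 26 and 3 of 24 rose (26 and 0 adjusted over the list alone). Camera called both lists up (adjusted p = 5.71e-11 for each in the 6-point table, 0.000530 and 0.00419 in the 8-point table), with adjusted p = 0.508 for each and 0.535 and 0.577 with an estimated correlation. General stress genes of SigB were called up (adjusted p = 0.000155 and 0.000530, and adjusted p = 0.542 and 0.577 with an estimated correlation), although 4 of 24 and 2 of 25 rose (8 and 1 adjusted over the list alone). Their sum was highest within the curves, at 15110 CPM (14606 to 15627) at OD600 1.7 against 2408 CPM at OD600 0.4 and 6638 CPM at OD600 3.2. The 8-point table had 3447 CPM at OD600 0.5, 23555 CPM (22992 to 24129) at OD600 1.3 and 9332 CPM at OD600 6.0.

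Several groups were highest in the middle of a curve. Genes of acetoin and acetate use held 427 CPM at OD600 0.4, 82307 CPM (80785 to 83850) at OD600 2.0 and 6144 CPM at OD600 3.2. They held 9315 CPM at OD600 1.6, 677 CPM at OD600 5.3 and 12530 CPM at OD600 6.0 of the 8-point table. Inositol use genes held 27162 CPM (26140 to 28214) at OD600 2.7 and 4554 CPM at OD600 3.2, and 8422 CPM at OD600 1.6 and 531 CPM at OD600 2.8 of the 8-point table. TCA cycle genes held 132767 CPM at OD600 2.7 of the 6-point table and 117726 CPM at OD600 1.6 of the 8-point table. The chaperone and protease genes under HrcA and CtsR held 40517 CPM (39690 to 41358) at OD600 1.7, against 8116 CPM at OD600 0.4 and 5289 CPM at OD600 3.2, and 20695 CPM at OD600 1.3 of the 8-point table. These levels are of single libraries and were not tested against each other.

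Camera called 3 of these lists up in the 6-point table: TCA cycle, where 2 of 12 rose (7 adjusted over the list alone, adjusted p = 0.00478, and adjusted p = 0.539 with an estimated correlation), acetoin and acetate use, with 1 of 9 (7 adjusted over the list alone, adjusted p = 0.00475, and adjusted p = 0.542 with an estimated correlation), and inositol use, with 1 of 12 (10 adjusted over the list alone, adjusted p = 0.00103, and adjusted p = 0.542 with an estimated correlation). The TCA call was lost without OD600 0.4 (adjusted p = 0.0740). Of their members in the 6-point table, sucD of the TCA cycle rose (1.70, SE 0.49), and acoA of acetoin use had a slope of 3.68 (SE 1.29, adjusted p = 0.0692) that did not pass. Purine synthesis genes were called up in the 6-point table, with 6 of 13 that rose, purL among them (1.46, SE 0.37; 8 adjusted over the list alone, adjusted p = 0.00478, and adjusted p = 0.508 with an estimated correlation). None of these 4 lists was called in the 8-point table, where 0, 2, 0 and 0 members rose (0, 2, 0 and 0 adjusted over the list alone). The iron uptake list went up in the 6-point table (adjusted p = 0.0207, and adjusted p = 0.595 with an estimated correlation; 1 of 19 rose, 0 adjusted over the list alone; adjusted p = 0.713 without OD600 0.4). It went down in the 8-point table (adjusted p = 0.0290, and adjusted p = 0.598 with an estimated correlation; 2 of 17 fell, 1 adjusted over the list alone), and that call was lost without OD600 5.3 (adjusted p = 0.119) or OD600 6.0 (adjusted p = 0.260). Whether the lists differ between the tables was not tested at the level of lists.

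4 lists were called up in the 8-point table and not in the 6-point one, a difference that was not tested. Neither competence nor cannibalism genes were tested as a list in the 6-point table, since 1 competence gene and 0 of 11 cannibalism toxin genes reached the filter. Camera made no call in that table for 7 subtilosin genes (adjusted p = 0.113) or 10 early sporulation genes (adjusted p = 0.258). Of 11 competence genes, for DNA uptake, 9 rose in the 8-point table (10 adjusted over the list alone), comFA by 2.68 (SE 0.36), and the summed genes held 880 CPM at OD600 3.6, 5546 CPM (4637 to 6581) at OD600 5.3 and 8456 CPM (7305 to 9736) at OD600 6.0. These 2 intervals are too narrow, since 10 cells held 71 of 130 UMIs at OD600 5.3 and 94 of 192 at OD600 6.0. Camera gave adjusted p = 2.41e-08, and adjusted p = 0.241 with an estimated correlation. Of 4 cannibalism toxin genes 3 rose (3 adjusted over the list alone), skfA by 3.54 (SE 0.49). The list test (camera) gave adjusted p = 0.000377, and adjusted p = 0.241 with an estimated correlation. Of 8 subtilosin genes, for an antimicrobial peptide, 6 rose (8 adjusted over the list alone), albA by 1.94 (SE 0.62), and the sum was highest at OD600 3.6 with 8708 CPM. By camera the list had adjusted p = 0.00802, and adjusted p = 0.577 with an estimated correlation. Of 6 early sporulation genes 2 rose (4 adjusted over the list alone, with 1 that fell), rapA by 2.76 (SE 0.32) to 25265 CPM and sigF, the first forespore sigma factor, by 1.80 (SE 0.37). The list held 499 UMIs at OD600 6.0, most of them of rapA, so its summed level there is mainly that of 1 gene and is not a measure of sporulation. Camera gave adjusted p = 0.0276, and adjusted p = 0.241 with an estimated correlation.

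In all, camera called 15 lists up and 5 down of 33 tested in the 6-point table and 14 up and 6 down of 33 in the 8-point table, and none held with an estimated correlation. fry, a rotation test of whether a list's genes move one way on balance, passed 11 and 17 lists. Camera made no call in either table for the HrcA and CtsR genes, other heat-inducible genes, ATP synthase, glycolysis, gluconeogenesis, PBSX prophage, branched-chain amino acid use, pyrimidine synthesis or uptake of ribose, glycerol and maltose, and of these lists fry passed glycolysis in the 8-point table (adjusted p = 0.0268). Some of their members were called. Of the uptake genes 2 rose and 6 fell of 17 in the 6-point table (3 and 7 adjusted over the list alone) and 4 of 16 fell in the 8-point table (4 adjusted over the list alone). Of 5 pyrimidine synthesis genes 2 fell in each table (2 adjusted over the list alone in each), and of 4 gluconeogenesis genes 1 rose in each (3 and 1 adjusted over the list alone). Genes that fell in the 8-point table were 2 of 9 of glycolysis (2 adjusted over the list alone), 2 of 7 other heat-inducible genes (1 adjusted over the list alone) and 1 of 8 branched-chain amino acid use genes (0 adjusted over the list alone). Of the HrcA and CtsR genes 1 of 12 and 2 of 11 fell (0 and 1 adjusted over the list alone), and no gene of ATP synthase or PBSX was called in either table. Among the lists without a call by camera, the median slope and camera's direction differed in sign for HrcA and CtsR and for glycolysis in the 6-point table (medians 0.03 and 0.08, camera down), and for ATP synthase and pyrimidine synthesis in the 8-point table (medians 0.06 and 0.11, camera down). Of the biofilm matrix genes tested, 2 of 2 rose in the 6-point table and 1 of 1 in the 8-point table, also adjusted over the list alone. Of the cold shock genes 2 of 3 and 2 of 2 fell (2 and 2 adjusted over the list alone); in the 6-point table camera made no call (adjusted p = 0.119) and fry passed the list (adjusted p = 0.0382). Bacilysin synthesis was not called in the 6-point table (adjusted p = 0.0974; 0 of 4 rose, 0 adjusted over the list alone), and 0 of 1 rose in the 8-point table (1 adjusted over the list alone). Genes of arginine synthesis, histidine use and tryptophan synthesis did not reach the filter in either table, and none of the sublancin list was measured.

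**Figure D1:**
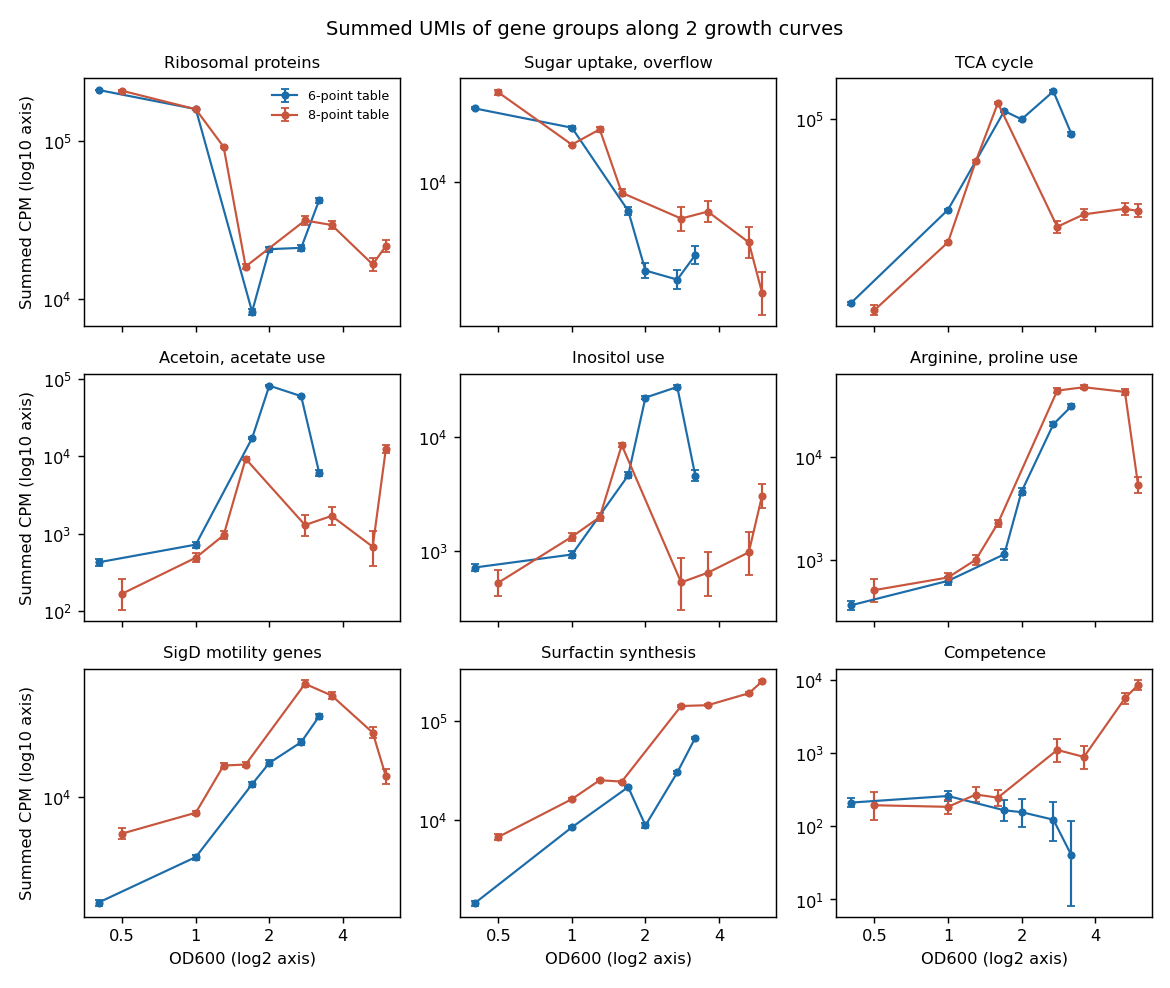
Summed CPM of 9 gene groups (log10 axis) against OD600 (log2 axis) in the 6-point table (blue) and the 8-point table (red); each point is 1 library and bars are exact 95% Poisson intervals for counting error. Ribosomal protein genes stand at 211105 CPM at OD600 0.4 and 8331 CPM at OD600 1.7, while surfactin genes reach 254326 CPM at OD600 6.0.

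The tables were then set against each other, since they share no library. Genes moved alike: across the 1437 genes tested in both, the slopes correlated with Pearson's r = 0.828 and Spearman's rho = 0.826 (genes are not independent replicates). Of 455 genes called in the 8-point table, 450 (98.9%) had a slope of the same sign in the 6-point table, and 330 (98.2%) of 336 called in the 6-point table had the same sign in the 8-point table. Over all 1437 genes, called or not, 83.7% had the same sign. 110 genes rose in both and 111 fell in both, against 23.5 and 28.1 for independent lists, and 0 were called in opposite directions. These numbers depend on the libraries: none was called in both without OD600 0.4 or OD600 2.7 of the 6-point table, which then had no calls, 64 rose and 30 fell in both without OD600 2.0, 48 fell without OD600 3.2 and 179 fell without OD600 1.7. In the 8-point table, leaving out OD600 0.5 gave 70 that rose and 65 that fell in both, and leaving out OD600 1.0 gave 73 that rose. Over the shared density range 54 rose and 5 fell in both, against 9.04 and 0.706 for independent lists. ptsG, treA, treP, rocB and putB are among the genes called the same way in both. pksE (adjusted p = 0.0514) and amyC (adjusted p = 0.129) were called in the 6-point table and did not pass in the 8-point table. A test of the difference of slopes over the shared density range, by edgeR, called 0 of 2209 genes (45 at an unadjusted p under 0.05; no other tool was run).

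**Figure D2:**
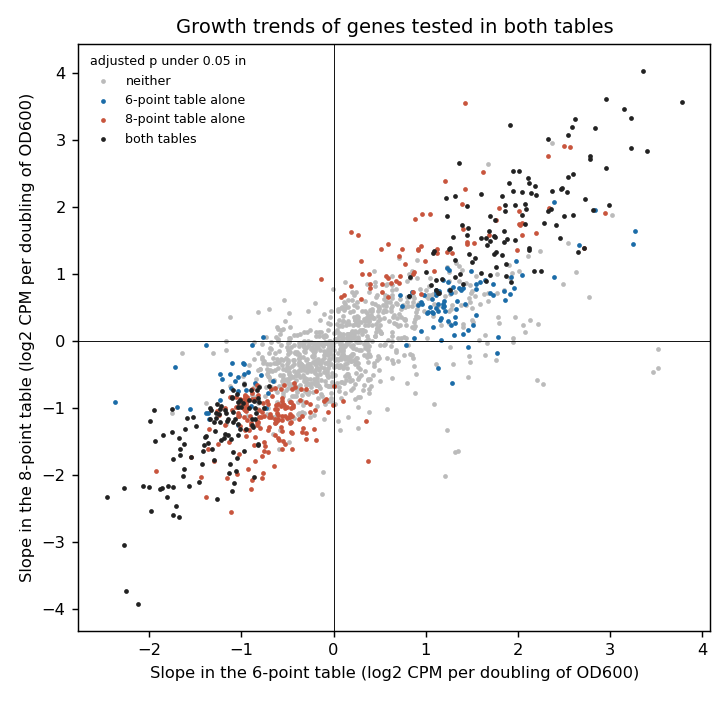
Slope of each gene in the 6-point table (horizontal axis) and in the 8-point table (vertical axis), in log2 CPM per doubling of OD600, for the 1437 genes tested in both; colours show where a gene's adjusted p was under 0.05. The 110 genes that rose in both tables and the 111 that fell in both are in black, at the upper right and the lower left.

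4 pairs of points with like density (OD600 0.4 with 0.5, 1.0 with 1.0, 1.7 with 1.6, 2.7 with 2.8) gave 2 libraries per point, a comparison chosen after the data were examined. The last pair was alike in density but not in every group. At OD600 2.7 and 2.8, acetoin and acetate use genes held 60389 and 1299 CPM and surfactin genes 30000 and 143918 CPM. Early sporulation genes held 2050 and 2098 CPM. From the first pair to the last, ptsG fell (-7.03, SE 0.71, adjusted p = 2.87e-05) as did rpsC (-3.13, SE 0.51) and fabHA of fatty acid synthesis (-4.46, SE 0.81). rocA (7.59, SE 0.71), oppA (6.77, SE 0.81), ilvB (7.16, SE 0.87), hag (3.45, SE 0.57) and srfAB (4.26, SE 0.64) rose. In edgeR's quasi-likelihood fit with the table as a covariate 435 genes were higher and 405 lower at the last pair among 2177 tested, and 939 differed between any of the 4 points. Of the ribosomal protein genes 51 of 55 fell (51 adjusted over the list alone), of the SigB genes 21 of 26 rose (22 adjusted over the list alone), and of the TCA cycle genes 7 of 12 rose (9 adjusted over the list alone). Camera gave these 3 lists adjusted p = 6.03e-20, 1.79e-09 and 0.00145, and adjusted p = 0.254, 0.254 and 0.599 with an estimated correlation. It called 18 of 34 lists up and 5 down in this comparison, and none held with an estimated correlation. The ATP synthase list had a median of -0.03 and camera's direction up, with no call (adjusted p = 0.966).

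Single cells were used to ask whether a gene group was spread evenly over the cells of a library or held by a few. In the 6-point table, after thinning to 200 UMIs per cell, 76 of 1706 cells at OD600 0.4 had at least 3 UMIs of late motility genes, 4.45% (3.53 to 5.54), where an even spread gives 0.969%; 42 of them were at exactly 3 UMIs and 98 more cells had 1 fewer. At OD600 1.0 the share was 11.2% (9.51 to 13.1) against 5.25%, and in the 8-point table it was 49.5% (44.9 to 54.0) at OD600 1.3 against 61.3%. For surfactin genes the share was 1.88% (1.29 to 2.64) at OD600 0.4 of the 6-point table against 0.292%, but 26 of these 32 cells were at exactly 3 UMIs and 67 more had 1 fewer. At OD600 1.0 it was 23.1% (20.8 to 25.6), with 23.5% for an even spread inside the interval. In the 8-point table it was 25.3% (19.2 to 32.1) of 186 cells at OD600 0.5 against 15.2%, 46.3% (42.8 to 49.9) at OD600 1.0 against 63.1%, 62.5% (58.0 to 66.8) of 485 cells at OD600 1.3 against 88.2%, and 62.1% (57.0 to 66.9) at OD600 1.6 against 86.8%. With a fixed minimum of 3 UMIs, an uneven spread raises the share where a list has few UMIs per cell and lowers it where it has many, so shares on either side depart from an even spread and are not opposite results. The even spread was computed from all cells of a library and the share from cells with at least 200 UMIs. A profile that differs between deep and shallow cells would also part the 2, and this was not tested. The binomial also takes the UMIs of a list as independent draws. Joint counts of neighbouring genes, as within 1 operon, would part the 2 as well, and this was not tested for the surfactin genes. PBSX prophage genes, for a defective phage, were held by few cells: 518 of their 994 UMIs at OD600 0.4 came from 1 of 5202 cells, and at OD600 2.8 of the 8-point table no UMI was seen in 795 cells. Independent counts would allow up to 99.6 CPM there (3 counts, a 1-sided limit). UMIs held by so few cells are not independent, so this limit is too low. Over 12 lists and the libraries with at least 100 thinned cells, 27 of 72 list and library pairs lay above an even spread and 8 below. These numbers were 31 and 18 with at least 2 UMIs, 22 and 2 with at least 5, and 24 and 12 when thinned to 300 UMIs. Thinning to 200 UMIs leaves only libraries up to OD600 1.0 and 1.6 of the 2 tables, and without thinning 58.9% of 168 pairs lay above, against 37.5%, and 15 pairs below. Thinned to 50 UMIs with at least 2, a setting chosen after the data were examined, 62 of 144 pairs lay above and 12 below.

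A count of UMI pairs, chosen after the data were examined, used all cells of each library where a list had at least 5 expected pairs. It set pairs of UMIs in 1 cell, from genes of a list at least 20 genes apart, over the number given by the library's summed profile. The ratio was highest for PBSX genes, 531 and 613 at OD600 0.4 and 1.0 of the 6-point table and 153 and 442 at OD600 1.0 and 1.6 of the 8-point table. At OD600 0.4 it rests on 117 gene pairs of 31 genes. All are genes of 1 prophage, so the distance does not part them as it parts genes from separate places on the chromosome. Competence genes had ratios of 17.1 at OD600 5.3 and 12.3 at OD600 6.0, where 192 UMIs lay in 45 of 849 cells and 10 cells held 94 of them, and 1.02 at OD600 0.4 of the 6-point table. Inositol use genes had ratios of 3.41, 8.32 and 4.50 at OD600 1.7, 2.0 and 2.7 and of 4.93 at OD600 1.6 of the 8-point table, and 1.39 at OD600 1.3, inside the 95% range of random lists, which ended at 1.48. These rest on 11 gene pairs of 12 genes. Late motility genes lay between 1.66 and 2.41 in the 6-point table and between 0.986 and 1.79 in the 8-point table. The 95% range of random lists of like expression ended at 2.41 and 2.08 for competence at OD600 5.3 and 6.0. Of 293 list and library pairs computed for 28 lists, 91 reached the upper end of the range of their own 1000 random lists, without correction for their number.

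**Figure D3:**
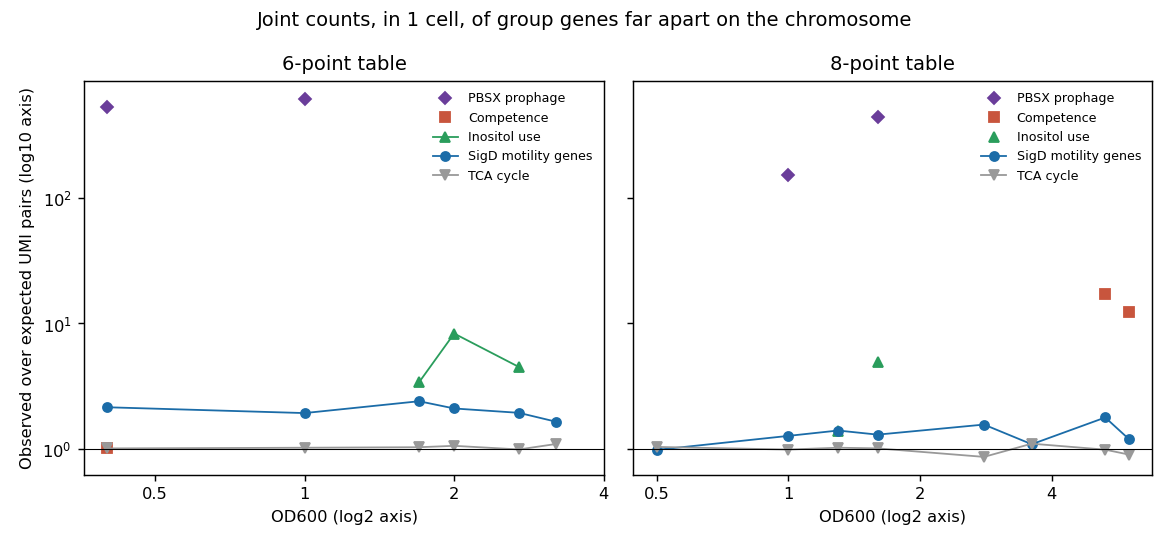
Observed over expected UMI pairs within 1 cell (log10 axis) for genes of 5 groups that lie at least 20 genes apart, against OD600 (log2 axis), in the 6-point (left) and 8-point (right) tables; each point is 1 library with at least 5 expected pairs. PBSX genes reach 613, competence genes 17.1, and TCA cycle genes stay near the line at 1.

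The 2-species table asks how often a barcode combination held more than 1 cell. By the species with most UMIs, 1222 cells were B. subtilis and 1460 E. coli, with medians of 4247 and 6260 UMIs. Ribosomal RNA columns held 88.6% of the B. subtilis UMIs, and the 14 largest E. coli columns, whose genes have no name in the tables used, held 96.0% of the E. coli UMIs. At least 10% of the UMIs came from the other species in 22 of 2682 cells, 0.820% (0.515 to 1.24), and the median share of the other species was 0.285%. This counts only mixtures of unlike species, so combinations of 2 cells of 1 species are not seen. The share was 1.33% in 528 cells of 1 sub-library and 0.696% in 2154 of the other. Heat-shocked cells were not compared with cells kept at the growth temperature, because no file used here ties a cell to either.

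**Figure D4:**
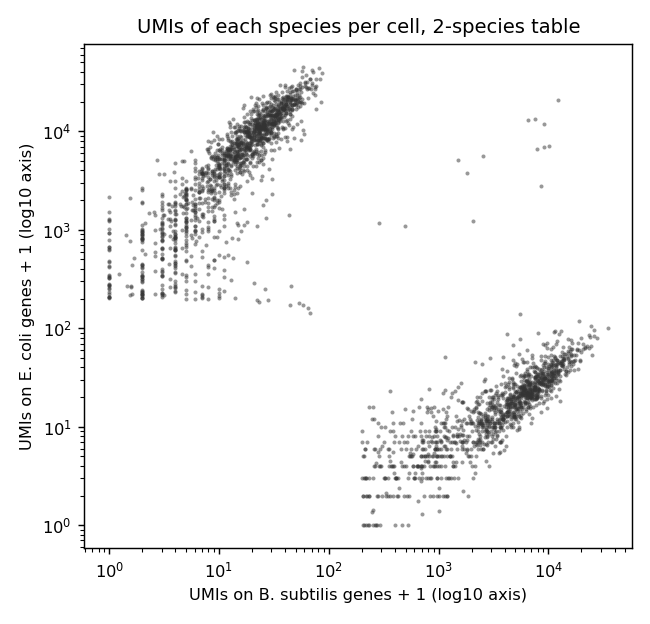
UMIs on B. subtilis genes (horizontal, log10 axis) and on E. coli genes (vertical, log10 axis) for each of 2682 cells of the 2-species table, with 1 added to each count; each point is 1 cell. Points away from both arms are the 22 cells with at least 10% of their UMIs from the other species and cells near that share.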

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

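The test that left out 1 gene at a time was chosen after the result was seen. In the B. subtilis cells of the 2-species table, the share of coding UMIs on the chaperone and protease genes under HrcA and CtsR fell into separate ranges by the barcode number in the cell names. It was picked out because the labels tie the first barcode to the sample and no comparison used these numbers. Over 45 numbers with at least 2000 coding UMIs the share ran from 1.28% to 8.10%, with a largest gap of 4.27 points between 2.10% and 6.38%. The SigB, other heat-inducible and ribosomal protein shares also moved with the number, by blocks given under other observations. A difference between the 2 sub-libraries is argued against, since 39 of 40 numbers (97.5%) lay on the same side of the middle of the gap, 4.24%, in both, although 7 values of sub-library 1 lay inside the gap. So is 1 gene of the list alone, since leaving out each of the 12 genes in turn parted the numbers in the same way, with a smallest gap of 2.23 points without groEL. The heat-shock treatment named in the labels stays open and untested, because no file used here maps a number to it.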

How the results depend on the processing

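Chosen after the results were seen were the refits with at least 50 UMIs per cell, thinning to equal UMIs, refiltered leave-outs, leave-outs of the 8-point table in the comparison of tables, each sub-library alone, and the lists with both tables in 1 fit. Depth limits the late libraries most, and the cause of each move below was not tested, except that leaving libraries out or thinning removes data. With libraries left out, where the naming rule fixes the sign of the slope, 603 gene and setting pairs were past the threshold and 115 were not, among them all 21 genes named in the 6-point table both without OD600 0.4 and without OD600 2.7. In the other refits no named gene changed sign, with 520 pairs past the threshold and 39 no longer past it. RLE scaling and total UMIs moved no count of trend calls by over 1.5 times. The labels gave no pairs, because the groups compared share fewer than 2 replicate numbers. The only pairing was by table, as a covariate in the fit of the matched points (840 genes, 827 without it). The planned refits of the growth tables with at least 400 UMIs per cell were not run, as late libraries hold few or no such cells, and no alternative of the heat-shock comparison was run.

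Among genes of the 6-point table, 208 rose and 164 fell. With the rank of OD600 110 rose and 80 fell, with linear OD600 123 rose, with both tables in 1 fit 411 rose and 456 fell, with DESeq2 405 rose and 285 fell, and without the filter 284 fell. Thinned to equal UMIs, 101 rose and 33 fell, and 7 calls changed sign. The upper against the lower OD libraries gave 0 and 0 (edgeR, with 292 at an unadjusted p under 0.05; no other tool was run). Leaving out 1 library gave 0 to 331 that rose and 0 to 297 that fell; the zeros are without OD600 0.4 (347 at an unadjusted p under 0.05 in edgeR) and without OD600 2.7 (641), and the highest counts without OD600 1.7. Among those of the 8-point table, 215 rose and 278 fell. Linear OD600 gave 125 that rose, both tables in 1 fit 411 and 456, at least 50 UMIs per cell 126 that rose beside 286 that fell, and thinning 100 and 34, with 4 calls of changed sign. Leaving out 1 library gave 84 to 248 and 99 to 289, the lowest without OD600 0.5 with genes filtered anew, where 638 genes were tested, and the highest without OD600 1.6; with refiltering 95 rose and 120 fell without OD600 1.0, and 136 rose and 179 fell without OD600 1.3.

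The spline called 492 and 534 genes. Without the filter it called 325 and 907, with both tables in 1 fit 1062, and the quadratic called 91 in the 6-point table. Leaving out 1 library gave 681 (OD600 1.7) to 1080 (OD600 1.0) and 276 (OD600 2.8) to 642 (OD600 1.6). The whole 6-point range lies above the full count, and these fits leave few residual degrees of freedom. For lists, the estimated correlation gave 0 up and 0 down in each table (limma's camera; fry passed 11 and 17). By fry 8 passed up and 3 down in the 6-point table; leaving out 1 library gave 3 to 5 lists down there, the lowest without OD600 0.4, and 3 to 6 in the 8-point table, the lowest without OD600 0.5. The iron uptake list of the 6-point table turned down with both tables in 1 fit (adjusted p = 0.677). In that fit TCA cycle (adjusted p = 0.0825), acetoin and acetate use (0.0520), inositol use (0.147), purine synthesis (0.628) and early sporulation (0.0825) lost their calls, and iron uptake did in the 8-point table with at least 50 UMIs per cell (0.0722). Over the shared density range 100% and 99.7% of calls had the same sign, and with 1 library left out 97.3% to 99.6% and 94.3% to 99.2%. Called in both tables were 110 that rose and 111 that fell, but 54 and 5 over that range, 63 that rose with at least 50 UMIs per cell, and 0 to 136 and 0 to 179 with 1 library left out, the lowest without OD600 0.4 or 2.7 and the highest without OD600 1.7 of the 6-point table. Species mixing was 1.33% in sub-library 1 alone. Without thinning, 58.9% of list and library pairs lay above an even spread.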

Other observations

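All tests in this part were chosen after the results were seen. Arginine synthesis genes, which make arginine from glutamate, held 25498 CPM (23469 to 27657) at OD600 6.0 of the 8-point table and 127 CPM (26.2 to 371) at OD600 5.3. Histidine use genes held 6134 CPM (5160 to 7238) at OD600 6.0 and 254 CPM at OD600 5.3. At the same step arginine and proline use genes went from 42884 to 5345 CPM, plipastatin genes from 7874 to 1314 CPM and gluconeogenesis genes from 18584 to 1665 CPM. Subtilosin genes held 8708 CPM at OD600 3.6 and 263 CPM at OD600 6.0. Intervals cover counting error only, and each point is 1 library with no replicate.

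The chaperone and protease genes under HrcA and CtsR had these shares by barcode number in the B. subtilis cells of the 2-species table. In percent of coding UMIs, numbers 1 to 12 held 6.71, 7.15, 7.16, 7.03, 6.84, 7.56, 6.60, 6.96, 7.22, 7.30, 6.38 and 7.08. Numbers 13 to 24 held 7.48, 8.10, 7.23, 7.59, 7.20, 7.37, 7.46, 6.86, 7.69, 7.20, 6.75 and 6.97. Numbers 25 to 36 held 1.44, 1.60, 1.47, 2.10, 1.60, 1.81, 1.46, 1.81, 1.46, 1.62, 1.59 and 1.28. Numbers 37, 38, 39, 41, 42, 43, 44, 45 and 46 held 1.54, 1.74, 1.72, 1.30, 2.00, 1.56, 1.33, 1.66 and 1.55; number 40 had too few coding UMIs, under 2000. The next values are in the same order of the numbers, from 1 to 46 without 40. SigB general stress genes held 0.996, 1.36, 1.03, 1.16, 1.30, 1.11, 1.12, 1.14, 1.18, 1.14, 0.788, 1.32, 1.26, 1.54, 1.16, 1.36, 1.14, 0.921, 1.12, 0.729, 0.981, 1.21, 1.16, 0.912, 0.460, 0.710, 0.421, 0.484, 0.421, 0.366, 0.579, 0.450, 0.539, 0.414, 0.332, 0.422, 0.596, 0.588, 0.398, 0.437, 0.677, 0.747, 0.527, 0.501 and 0.554 percent. Other heat-inducible genes held 1.04, 1.02, 1.06, 0.858, 1.05, 1.32, 1.02, 0.922, 0.945, 1.03, 0.908, 1.15, 1.02, 0.987, 0.896, 1.04, 1.03, 1.03, 1.12, 1.03, 1.03, 1.07, 1.02, 0.969, 0.693, 0.953, 0.771, 1.08, 0.573, 0.757, 0.736, 0.828, 0.682, 0.837, 0.745, 0.798, 0.627, 0.918, 0.749, 0.681, 0.734, 0.722, 0.625, 0.710 and 0.632 percent. Ribosomal protein genes held 16.5, 15.9, 19.8, 16.6, 18.3, 16.9, 17.5, 19.4, 16.5, 17.8, 18.1, 17.3, 17.7, 16.2, 16.7, 16.7, 17.5, 19.1, 18.4, 17.9, 17.2, 17.8, 18.3, 17.7, 22.1, 19.1, 22.4, 18.9, 22.9, 20.7, 21.7, 21.7, 22.7, 20.8, 21.5, 23.3, 20.01, 21.7, 22.3, 21.6, 20.7, 22.1, 21.4, 23.7 and 21.2 percent. By blocks of 12 numbers in this order, the last with 9, the ranges were 6.38 to 7.56, 6.75 to 8.10, 1.28 to 2.10 and 1.30 to 2.00 percent for HrcA and CtsR genes. They were 0.788 to 1.36, 0.729 to 1.54, 0.332 to 0.710 and 0.398 to 0.747 percent for SigB genes, and 0.858 to 1.32, 0.896 to 1.12, 0.573 to 1.08 and 0.625 to 0.918 percent for other heat-inducible genes. For ribosomal protein genes they were 15.9 to 19.8, 16.2 to 19.1, 18.9 to 23.3 and 20.01 to 23.7 percent. The blocks of 12 were chosen after the values were seen and no test was made between them. Labels put none of these numbers in a group.

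At OD600 2.0 of the 6-point table, 100 of 1694 cells with at least 30 UMIs had at least 10% of them on ribosomal protein genes, and they held 50.8% of that list's UMIs in these cells. Their median was 43 UMIs against 49 in the rest. The cells were picked by a share of their UMIs, which shallow cells pass more easily by sampling, so the medians cannot decide on depth. Over the other genes 86.0% of the 100 cells were closest to an earlier library (66 to OD600 1.0 and 19 to OD600 0.4), against 2.01% of the rest, so cells of an earlier library counted under OD600 2.0 are a candidate explanation. In this paragraph CPM are per UMIs outside the ribosomal protein genes, not per total UMIs. All 5 lists computed lay between the rest and OD600 1.0: in these cells, the rest and at OD600 1.0, sugar uptake held 21150, 2171 and 23035 CPM, iron uptake 14030, 7810 and 15534, TCA cycle 49838, 106376 and 46906, acetoin and acetate use 16334, 88425 and 861, and late motility 9004, 16742 and 4983. A subpopulation of the culture with such a profile stays open and was not tested.

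Competence genes were counted together in the same cells at OD600 5.3 and 6.0, with ratios of observed to expected pairs of 17.1 and 12.3. The expected number already uses the UMIs of each cell, so depth differences between cells were allowed for and not tested apart. For 1000 random lists of like expression the 95% ranges ended at 2.41 and 2.08. Against cells drawn at large from an earlier library of the table stands the highest level at a lower density, 1095 CPM, below the interval of 4637 to 6581 CPM at OD600 5.3. That interval takes UMIs as independent, but 10 cells held 71 of 130, so it is too narrow and the argument is weaker than it shows. The level of 1095 CPM cannot decide on a few single cells: at OD600 2.8, 1 of 795 cells held 21 of 34 competence UMIs. Cells that differ in competence expression may account for the ratio of 12.3, as a hypothesis found on the same data.

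Reordering the OD600 values over the libraries, with 100 orders per table and the real one included, left only the real order with as many calls. For the 6-point table the real order gave 372 genes and the highest other 0, a share of 1 in 100. For the 8-point table the real order gave 493 and the highest other 262, again 1 in 100, the smallest share that 100 orders can give. A random order of the libraries is thus argued against for the number of calls in each table. Reordering cannot part OD600 from anything else that moves along the curve with it, such as depth.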
